A study of Mus musculus with 4 samples.

How the data were processed

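The samples were cells from the limbs of mouse fetuses at E17.5, sorted for viability (7-AAD) and GFP from Pax7-nGFP fetuses of the C57BL/10ScSnJ background (WT) or of the mdx genotype. Libraries were prepared with the 10x Genomics single cell 3' v3 chemistry, per the labels' protocols, which reads the 3' ends of polyadenylated transcripts and tags each captured molecule with a unique molecular identifier (UMI). The deposited values are whole-number UMI counts per gene and barcode, made by the authors with Cell Ranger 7.1.0 on the mouse build mm10 (GRCm38), per the submitters' processing notes. Whether intronic reads were counted is not given in the sources used here. The gene tables held 32285 gene IDs with symbols, of which 32235 had a position in the GENCODE vM21 annotation of GRCm38 that was used for coordinates. No GFP transgene was among the genes, so the gate could not be checked from the counts. Count matrices of 3 of the 4 libraries were used (WT 1, WT 2 and mdx 1). For mdx 2 a list of 18970 barcodes was read, and its counts were not analysed here.

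Groups came from the labels. Cell filters, clustering settings, cell type markers, gene lists, tests and the rule for named genes were fixed before the data were examined. Cells with at least 1000 UMIs, at least 500 genes and under 10% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet in scanpy 1.11.5, and the highest scores were removed at 0.8% per 1000 barcodes (1143, 1213 and 1071 cells of WT 1, WT 2 and mdx 1), because the automatic threshold called 246, 268 and 0 cells. Values normalized to library size and log transformed were reduced to 30 components over 2000 variable genes and clustered with 15 neighbours and Leiden (leidenalg 0.10.2) at resolution 1. Ribosomal, mitochondrial, haemoglobin and sex-linked genes and the dystrophin complex, polarity, Notch and immediate early lists were left out of the variable genes.

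Clusters were named from 13 marker lists (120 names, all matched) by the number of markers among the 10 leading genes by fold (pseudocount 10 CPM) and then by the mean marker score. The scoring rule was set after the counts were seen, while the markers were fixed earlier. A cluster stayed unnamed where markers of another class led it, where fewer than 3 markers were detected, or where its median UMI count, multiplied by 3, stayed under that of its libraries with no marker of its class among the leading genes. "Stem cell-like", "committed myoblast-like" and "myocyte-like" refer to these names. Myogenic cells are the cells of these classes plus 2 unnamed clusters with Tagln among their leading genes (Tagln clusters). For shares of cells with a UMI and for phases, each cell was thinned to 2000 UMIs, and shallower cells were left out. A cell was called in S, G2 or M phase above 3 UMIs of the S list or above 6 UMIs of the G2 and M list, the 95th percentiles of 1858 cells in the myocyte-like clusters 8 and 15. Shares have 95% exact binomial (Clopper-Pearson) intervals, which cover counting error only, and no test, since 2 libraries against 1 cannot give a one-sided p below 0.333.

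UMI counts were summed per library and class, and the sums were compared between mdx 1 and the WT libraries with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr at 10 and 15 counts, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. With 1 mdx library the residual degree of freedom comes from the WT pair, the mdx library is assumed to vary like the WT libraries, and library and genotype cannot be told apart. The edgeR fits drew the spread of a gene almost wholly from the trend over all genes (common biological coefficient of variation 7.70%, 7.68%, 7.95% and 8.10% in the stem cell-like, committed myoblast-like and myocyte-like classes and all myogenic cells). A gene that differed between the WT libraries can therefore still pass, and WT values are given per library. Changes from the stem cell-like to the myocyte-like class, and their difference in mdx 1, were tested with edgeR on the sums of 3 classes in 3 libraries with library as a block. CPM values were computed by edgeR after TMM scaling, and fold changes are log2 values with standard errors (SE).

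The 24 gene lists (598 names, 595 matched) were: dystrophin complex, polarity and asymmetric division, Notch pathway, myogenic commitment, contractile apparatus, fetal myogenesis switch, quiescence, extracellular matrix of the niche, matrix receptors and adhesion, S phase, G2 and M phase, CDK inhibitors and p53 targets, immediate early and dissociation stress, interferon response, TGF-beta and BMP response, Wnt response, FGF and MAPK feedback, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded, ribosomal proteins, sex-linked, histone genes, and imprinted growth network. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 with Benjamini-Hochberg adjustment over the lists. No list passed in any class with an estimated correlation. With 3 libraries that version rests on the residual degree of freedom of the WT pair, so few lists could pass it. Its results cannot tell whether inter-gene correlation accounts for a call. The histone list of the stem cell-like class did not pass it although its estimated correlation was -0.029. Other estimates lay far above the preset. In the myocyte-like class they were 0.68 for the contractile apparatus, 0.58 for G2 and M phase and 0.73 for S phase. In all myogenic cells the contractile apparatus had 0.70. The p-values of camera at the preset may therefore be far too small for such lists. Single values of 2 genes of the dystrophin complex list are not reported here.

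Named genes were Dmd, Pax7, Myf5, Myod1, Myog, Mki67, Cdkn1a, Notch3, Hey1, Heyl, Utrn, Pard3, Mark2, Egfr and Aurka in every comparison; the 10 genes with the largest fold change each way among those past the threshold, with a mean of at least 20 CPM and an mdx 1 value beyond both WT libraries by more than these differ; and up to 4 members of each list with the smallest p. Haemoglobin, sex-linked and predicted genes were left out of the ranked names and are given as counts. Histone genes and short ribosomal and mitochondrial transcripts belong to families with near-identical copies, and their counts could be split between copies.

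On simulated counts made from the real means and library sizes with 200 changed genes, edgeR recovered 100% of 2-fold and 88% of 1.5-fold changes in the stem cell-like class with 4 false calls. The values were 98%, 58% and 10 in the committed myoblast-like class, 100%, 76% and 9 in the myocyte-like class, and 100%, 80% and 7 in all myogenic cells. The step across classes recovered 100% of 4-fold and 100% of 2-fold changes with 9 false calls. The interaction recovered 100% of 4-fold and 99% of 2-fold changes with 7 false calls. These counts follow the fit's own trend and hold no library shift, so false calls in the real data can be more. Recovery below 20 CPM was not simulated. Most genes called in the stem cell-like class and in all myogenic cells had a mean below that level. In the stem cell-like class 6201 of 16639 genes tested had a mean of at least 20 CPM.

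Alternatives chosen before the data were examined were DESeq2 1.42.0 in place of edgeR, its size factors (RLE) in place of TMM, no filter on low counts, no doublet removal, a stricter cell filter (2000 UMIs, 1000 genes and under 5% mitochondrial UMIs), resolutions 0.5 and 2, components centred per library, cells thinned to 2000 UMIs, classes assigned from marker scores for the shares, camera with an estimated correlation, and leaving out each WT library. Alternatives added after the data were seen were the Tagln clusters joined to the stem cell-like class, single clusters alone, removal of droplets with 20 or more haemoglobin UMIs, WT libraries alone for the change across classes, and classes assigned from marker scores for the counts of genes. In that last setting 18.0% of cells lay near a boundary between scores. The other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.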

Results

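Single cells were profiled from the limbs of mouse fetuses at E17.5, when the later fetal wave of muscle fibres forms. The fetuses carried Pax7-nGFP, a reporter that puts nuclear green fluorescent protein (GFP) in cells with an active locus of Pax7, the transcription factor of muscle stem cells, and live GFP-positive cells were sorted. WT fetuses were on the C57BL/10ScSnJ background, and mdx fetuses carried a nonsense allele of Dmd, the X-linked gene of dystrophin, which links the cytoskeleton to the matrix at the muscle membrane. The series addresses whether the absence of dystrophin alters polarity and entry into differentiation in these cells. The labels call the libraries of each genotype biological duplicates. With 1 mdx library, p-values against WT hold no spread between mdx libraries. They rest on the WT pair, with the spread of a gene drawn almost wholly from the trend over all genes. The 2 WT libraries and 1 mdx library (mdx 1) were compared, and mdx 2 was not analysed here. WT 1, WT 2 and mdx 1 held 13085, 13036 and 13303 barcodes with 92267778, 96298739 and 87832257 unique molecular identifiers (UMIs), of which 9775, 10415 and 8992 cells were kept with medians of 7369, 7427 and 7587 UMIs per cell. Summed over all cells, log2 CPM values correlated across 12701 genes with Pearson's r of 0.997 between the WT libraries and 0.994 and 0.993 between mdx 1 and WT 1 or WT 2 (genes are not independent replicates), and each pair of libraries differed by more than sampling noise (chi-square per degree of freedom 51.8, 118 and 81.7). With 1 mdx library, genotype and library cannot be told apart in any comparison with WT.

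The 29182 cells fell into 24 clusters, most of them muscle cells at successive steps of myogenesis. The muscle stem cell-like class (clusters 0, 1, 2, 7, 9, 11, 14 and 16) held cells with high Pax7 and Myf5, the transcription factor of early myogenic cells, and included clusters led by Cenpf (mitosis) and by the replication-dependent histone gene Hist1h1b (S phase). A committed myoblast-like class (cluster 3), led by Slc24a3 and the replication genes Ung and Cdc6, had no class marker among its 10 leading genes and was named from marker scores. Its Myod1 (the factor of commitment) and Myog (the factor of terminal differentiation) levels were 161 and 358 CPM. The myocyte-like class comprised cluster 5 (led by Myog and the fusion genes Mymx and Mymk), cluster 6 (led by the mitotic gene Ube2c and by Myog), cluster 8 (led by Myo16 and the troponin genes Tnnt2 and Tnni1) and cluster 15 (led by the myosin light chain genes Mylpf and Myl1 and by skeletal actin, Acta1). The committed score of cluster 3 was 0.32, below those of clusters 5, 6, 8 and 15 (1.36, 1.10, 1.56 and 1.56). Clusters 5 and 6 scored lower for the myocyte markers (0.85 and 0.65) than for the committed ones, and were named from markers among their leading genes. The border between these classes therefore depends on the naming rule. The unnamed clusters 4 and 10 (Tagln clusters), with the smooth muscle marker Tagln among their leading genes, had 365 and 397 CPM of Pax7 and were counted as myogenic. Small clusters resembled fibroblasts (Col1a1, Dcn), chondrocytes (Col2a1, Acan) and immune cells (Lyz2, Tyrobp). No cluster was named for the tenocyte, endothelial, pericyte, erythroid, Schwann cell, keratinocyte or neuron markers, and a mixed cluster led by keratin genes (Krt1, Krt10) and clusters of low UMI counts stayed unnamed.

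Dmd, the targeted gene (ENSMUSG00000045103; GRCm38 chromosome X, 82948870 to 85206141), had 192, 248 and 255 CPM in all myogenic cells of WT 1, WT 2 and mdx 1, from 13550, 19056 and 17521 UMIs. In the stem cell-like class it had 240, 320 and 313 CPM, in the committed myoblast-like class 114, 163 and 130 CPM, and in the myocyte-like class 91.0, 123 and 120 CPM. Its log2 fold changes in mdx 1 were 0.21, 0.16, -0.10 and 0.16, with edgeR adjusted p of 0.438, 0.716, 0.917 and 0.546, so a difference was not detected. A 3' tag lies outside the nonsense codon, so these values do not check the allele or the label. Nor can it tell apart transcripts of Dmd that share a 3' end. The values, here and across classes, are therefore for the gene as a whole and not for 1 isoform. Whether intronic reads were counted is not known, and if they were, the levels of this long gene, here and across classes, include unspliced RNA.

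Differentiating cells made up a smaller part of the mdx 1 library than of either WT library, and stem cell-like cells a larger part. After thinning to 2000 UMIs, Myog was detected in 25.8% (95% exact binomial interval 24.9 to 26.8), 29.6% (28.7 to 30.5) and 20.4% (19.5 to 21.3) of myogenic cells of WT 1, WT 2 and mdx 1. Pax7 was detected in 43.5% (42.4 to 44.5), 41.2% (40.2 to 42.2) and 47.6% (46.5 to 48.7). Both mdx 1 values lay beyond the WT pair by more than the WT libraries differed. Myf5 was detected in 13.4%, 12.2% and 14.3%, and mdx 1 lay beyond the WT pair by less than these differed. Myod1 gave 17.9%, 16.8% and 17.7%, within the WT range. Without thinning the shares were 36.8%, 41.4% and 31.0% for Myog, 77.8%, 73.5% and 82.7% for Pax7, 34.5%, 31.6% and 38.8% for Myf5 and 45.5%, 44.7% and 44.4% for Myod1. Thinning left out 102, 87 and 187 shallower myogenic cells. In non-muscle cells, which should lack these genes, the thinned shares were 11.4%, 8.02% and 6.02% for Myog, 6.06%, 1.85% and 4.63% for Pax7, 0.758%, 0% and 0% for Myf5 and 1.52%, 2.47% and 2.78% for Myod1. Median depths were 7615, 7646.5 and 7895.5 UMIs in myogenic and 6128, 6249.5 and 6239.5 UMIs in non-muscle cells. The 0 of 162 and 0 of 216 non-muscle cells with Myf5 in WT 2 and mdx 1 have exact upper limits of 2.25% and 1.69%.

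By cluster, the stem cell-like class took 56.0% (54.9 to 57.0), 54.5% (53.5 to 55.5) and 63.4% (62.4 to 64.5) of myogenic cells in WT 1, WT 2 and mdx 1, and the myocyte-like class 19.7% (18.9 to 20.5), 24.2% (23.3 to 25.04) and 13.6% (12.8 to 14.3). The committed myoblast-like class held 9.44%, 9.23% and 9.32%, and the Tagln clusters 14.9%, 12.1% and 13.7%. The mdx 1 share of the myocyte-like class was 0.619 times the WT mean. Within it the most differentiated cluster 15 was at 2.19%, 3.25% and 0.675%, cluster 8 at 4.62%, 7.19% and 2.49%, cluster 5 at 7.07%, 7.63% and 5.27% and the cycling cluster 6 at 5.81%, 6.09% and 5.14%. Genes that define this class had lower levels in its mdx 1 cells, so a share that needs no cluster is given beside these sizes: over all barcodes, thinned to 500 UMIs, Myog was detected in 13.5%, 15.02% and 9.38%. Among stem cell-like clusters, cluster 0, with Calcr among its leading genes, took 13.0%, 16.0% and 19.2%, and cluster 2, led by histone genes, 12.2%, 11.2% and 10.02%. Cluster 7, led by the growth factor gene Nrg1, took 4.86%, 4.26% and 7.33%, and cluster 14, led by Igf1 and Barx2, took 2.55%, 1.90% and 3.25%. Non-muscle cells were 1.46%, 1.69% and 2.62% of kept cells, a share that the GFP gate can set. Fibroblast-like cells were at 0.951%, 1.19% and 1.92%, immune-like cells at 0.194%, 0.202% and 0.411% and chondrocyte-like cells at 0.317%, 0.298% and 0.289%. The keratin-led cluster held 3.03%, 2.06% and 2.42% of kept cells. These are values with counting intervals and no test. With components centred per library the excess of stem cell-like cells in mdx 1 over the WT mean was 3.07 points in place of 8.20, and with shares of 43.7%, 40.3% and 45.1% mdx 1 lay beyond WT 1 by less than the WT libraries differed.

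**Figure D1:**
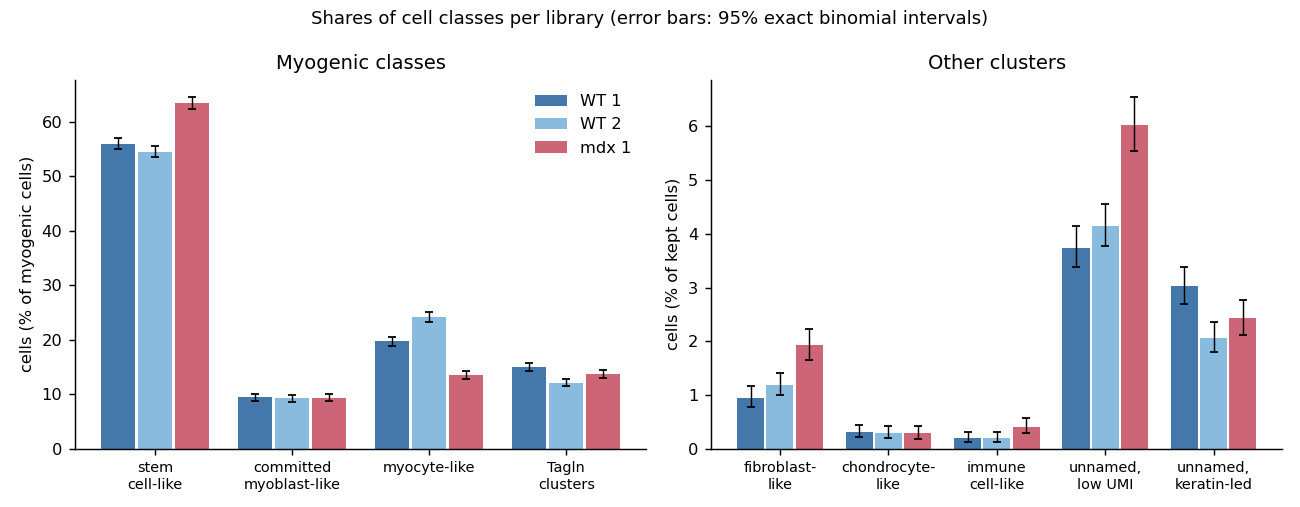
Bars give the share of myogenic cells (left, %) or of all kept cells (right, %) in each class for WT 1, WT 2 and mdx 1, with 95% exact binomial intervals. In mdx 1 the stem cell-like class stands at 63.4% against 56.0% and 54.5%, and the myocyte-like class at 13.6% against 19.7% and 24.2%.

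In the stem cell-like class of mdx 1, Hes1, Calcr and Ankrd1 rose and 9 of 15 histone genes fell, while no difference was detected in the factors of myogenic identity. Hes1, a transcriptional repressor induced by Notch, rose from 77.9 and 65.5 to 146 CPM (log2 fold change 1.03, SE 0.12, edgeR adjusted p = 3.21e-14). Calcr, the calcitonin receptor of quiescent muscle stem cells, rose from 19.4 and 22.4 to 35.6 CPM, Ankrd1, a target of the stretch-responsive YAP pathway, from 26.8 and 31.8 to 59.0 CPM, and the heat shock gene Hspa1a from 218 and 66.1 to 487 CPM. Hist1h1b, a linker histone made in S phase, fell from 829 and 930 to 528 CPM, and Igf2, a fetal growth factor, fell from 566 and 634 to 409 CPM. Pax7 had 414, 397 and 420 CPM, and no difference was detected for Pax7, Myf5, Myod1 or Myog, whose log2 fold changes were 0.05, -0.02, -0.03 and -0.08. Different shares of the clusters fill this class too, with more of cluster 0 and less of cluster 2 in mdx 1, and in cluster 0 alone the log2 fold changes were 0.94 for Hes1, 0.67 for Calcr and -0.59 for Hist1h1b, all past the edgeR threshold.

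By edgeR, 426 of 16639 genes tested passed in this class, 224 higher and 202 lower in mdx 1. They include 109 predicted genes and 4 haemoglobin genes. DESeq2 called 38 genes, 36 of them among the 426, and gave no adjusted p for 5484 of the genes tested. All 426 had the same sign, which carries little weight since both tools take the fold change from the same sums. The calls for Hes1, Ankrd1, Calcr, mt-Nd3, Ccn1, Fosb, Camk1d and Hist1h1b were among those that DESeq2 kept. With components centred per library edgeR called 12 genes, with every cell thinned 133 and without a filter on low counts 4. Setting WT 1 or WT 2 apart in place of mdx 1 puts mdx 1 in the reference pair, so its difference from WT enters the fitted spread. The common biological coefficient of variation was then 10.3% and 10.8% against 7.70%. A count of genes from such a split is therefore no null rate and is not given. Of the always-named genes other than Hey1, none passed: Mki67, a proliferation marker, had a log2 fold change of -0.19, the cell cycle inhibitor gene Cdkn1a 0.11, the Notch receptor gene Notch3 0.12, its target Heyl 0.15, the dystrophin homologue Utrn 0.20, the polarity genes Pard3 and Mark2 0.13 and 0.14, the growth factor receptor gene Egfr 0.28 and the mitotic kinase gene Aurka 0.01.

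**Figure D2:**
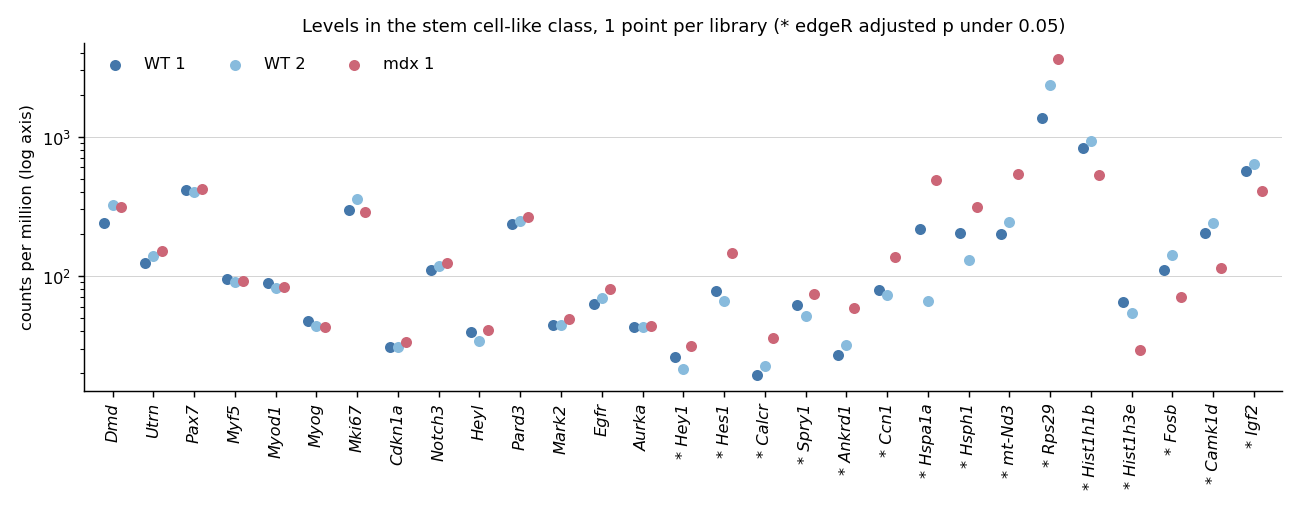
Each point is the level of a gene in the stem cell-like class of 1 library in CPM (log axis), and an asterisk marks genes past the edgeR threshold. Hes1 and Calcr lie higher in mdx 1 (146 and 35.6) than in both WT libraries, Hist1h1b lower (528), and Pax7 at 414, 397 and 420.

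Of the Notch pathway list (19 genes), 3 rose, 0 fell and 16 did not pass (3 and 0 adjusted over the list alone), with a median log2 fold change of 0.15. Beside Hes1, these were its relatives Hey1 (0.40) and Hey2 (0.89). The list moved up by camera (adjusted p = 0.000251, and adjusted p = 0.640 with an estimated correlation). Here and below, the value with an estimated correlation rests on the residual degree of freedom of the WT pair and cannot decide. Of the polarity and asymmetric division list (26), 0 rose or fell (0 adjusted over the list alone), the median was 0.11 and camera gave an adjusted p of 0.0745. In the dystrophin complex list (20), Dtna, a cytoplasmic dystrobrevin gene, rose by 0.54 with 28.9, 40.6 and 50.7 CPM and 19 did not pass (2 and 0 adjusted over the list alone). The median was 0.11 and camera gave an adjusted p of 0.0388 (adjusted p = 0.778 with an estimated correlation). That call ended with thinned cells, centred components, classes from scores or the Tagln clusters included. Quiescence genes (18) had 2 that rose, 1 that fell and 15 that did not pass (5 and 1 adjusted over the list alone). Calcr rose by 0.77 and Spry1, an inhibitor of growth factor signalling, by 0.40, while Fosb, a gene of the early response to stimuli, fell by 0.85. The median was 0.16 and camera gave 0.0355 (adjusted p = 0.640 with an estimated correlation), lost with thinned cells, classes from scores or the Tagln clusters included. Of the TGF-beta and BMP response list (22), 2 rose, 0 fell and 20 did not pass (3 and 0 adjusted over the list alone). Smad6, an inhibitor of BMP signals, rose by 0.66 and Bmp4, a ligand, by 0.60. The median was 0.21, with a camera adjusted p of 0.000117 (adjusted p = 0.640 with an estimated correlation). Matrix receptors and adhesion genes (23) had 1 that rose, the adhesion gene Mcam (0.39), 0 that fell and 22 that did not pass (1 and 0 adjusted over the list alone). Their median was 0.10 and the camera adjusted p 0.0388 (adjusted p = 0.640 with an estimated correlation), lost with the stricter filter, classes from scores or the Tagln clusters included.

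Histone genes were lower as a list, with fewer cells of the histone-led cluster 2 in mdx 1: of 15, 0 rose, 9 fell and 6 did not pass (0 and 9 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 1.51e-17, and adjusted p = 0.640 with an estimated correlation). Hist1h1e fell from 340 and 393 to 209 CPM, and Hist1h2ap had 113, 30.2 and 43.1 CPM, a fall that rests on WT 1 (log2 fold change 0.51 against WT 2 alone). In cluster 0 alone 4 of the 15 fell and the median was -0.45. Outside the list, the nucleosome histone gene Hist1h3e fell by 1.02. The histone list also had a median of -0.79 in non-muscle cells of the same libraries, where 4 of its 14 genes fell. Immediate early and dissociation stress genes (32) had 9 that rose, 2 that fell and 21 that did not pass (10 and 3 adjusted over the list alone, median 0.13; camera adjusted p = 2.97e-10, and adjusted p = 0.640 with an estimated correlation). The heat shock genes Hspa1a, Hspa1b and Hsph1 rose by 1.78, 1.48 and 0.90 and Ccn1, a secreted matrix protein gene and YAP target, by 0.83. Hspa1a and Hspa1b also rose in non-muscle cells (1.77 and 1.81) and differed between the WT libraries by -1.72 and -1.14 on the log2 scale. Mitochondrially encoded genes (13) had 2 that rose, 1 that fell and 10 that did not pass (2 and 1 adjusted over the list alone). mt-Nd3, a subunit gene of respiratory complex I, rose by 1.28 here and by 1.28 in non-muscle cells, mt-Atp8 rose by 0.53 and mt-Nd6 fell by 0.41. Their median was 0.11 and the camera adjusted p 0.0262 (adjusted p = 0.640 with an estimated correlation), lost with components centred per library. Contractile apparatus genes (23) had 0 that rose, 4 that fell and 19 that did not pass (0 and 9 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.000160, and adjusted p = 0.640 with an estimated correlation). Myl1, Tnni1, Tnnt2 and Mylpf fell by 0.65, 0.65, 0.56 and 0.55 from levels under 22 CPM in every library. In non-muscle cells, which should lack these transcripts, the contractile median was -0.20 with 2 of 14 genes fallen, and Myog fell from 78.2 and 47.2 to 24.2 CPM, so less free RNA of myocytes in mdx 1 is not excluded for these falls.

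The other lists did not pass camera in this class. In the oxidative phosphorylation list (43) 2 rose and 41 did not pass (2 and 0 adjusted over the list alone, median -0.10; camera adjusted p = 0.287), and in the ribosomal protein list (49) 3 rose and 46 did not pass (3 and 1 adjusted over the list alone, median -0.10; adjusted p = 0.425). The genes that rose, among them Atp5k (0.86), Rps28 (0.90) and Rps29 (1360, 2344 and 3639 CPM), encode short transcripts that also differed between the WT libraries. Myogenic commitment genes (20) had 1 that rose, the transcription factor gene Mef2c (0.65), 1 that fell, the fusion gene Mymx (-0.84), and 18 that did not pass (2 and 1 adjusted over the list alone), and their median of -0.02 and the upward direction of camera (adjusted p = 0.941) differ in sign. The fetal myogenesis switch list (11) had Mcam up and Eno3, a muscle enolase gene, down by 0.47, and 9 that did not pass (1 and 2 adjusted over the list alone, median 0.16; adjusted p = 0.363). FGF and MAPK feedback genes (17) had 2 that rose, Spry1 and Phlda1 (0.61), and 15 that did not pass (2 and 0 adjusted over the list alone, median 0.07; adjusted p = 0.0745). CDK inhibitors and p53 targets (20) had 1 that rose, the stress cytokine gene Gdf15 (0.73), with 2 and 0 adjusted over the list alone (median 0.12; adjusted p = 0.0931). The imprinted growth network (16) had the RNA gene Mirg up by 0.62 and Igf2 down by 0.55 (1 and 1 adjusted over the list alone, median 0.02, mean -0.001; adjusted p = 0.968). Glycolysis and hypoxia genes (24) had 1 that rose, the hexokinase gene Hk2 (0.52; 1 and 0 adjusted over the list alone), with a median of -0.07 against an upward camera direction (adjusted p = 0.941). By edgeR, 0 genes passed, also adjusted over the list alone, among the S phase (42, median -0.06; camera adjusted p = 0.108), G2 and M phase (52; -0.05; 0.136), extracellular matrix (26; 0.04; 0.456), interferon response (20; 0.17; 0.197), Wnt response (18; 0.16; 0.0761) and sex-linked (4; 0.18; 0.197) lists. The share of stem cell-like cells called in S, G2 or M phase after thinning was 85.7%, 85.1% and 83.7% in WT 1, WT 2 and mdx 1, beside 3951, 3863 and 3819 CPM of the S list and 8042, 8402 and 8240 CPM of the G2 and M list.

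**Figure D3:**
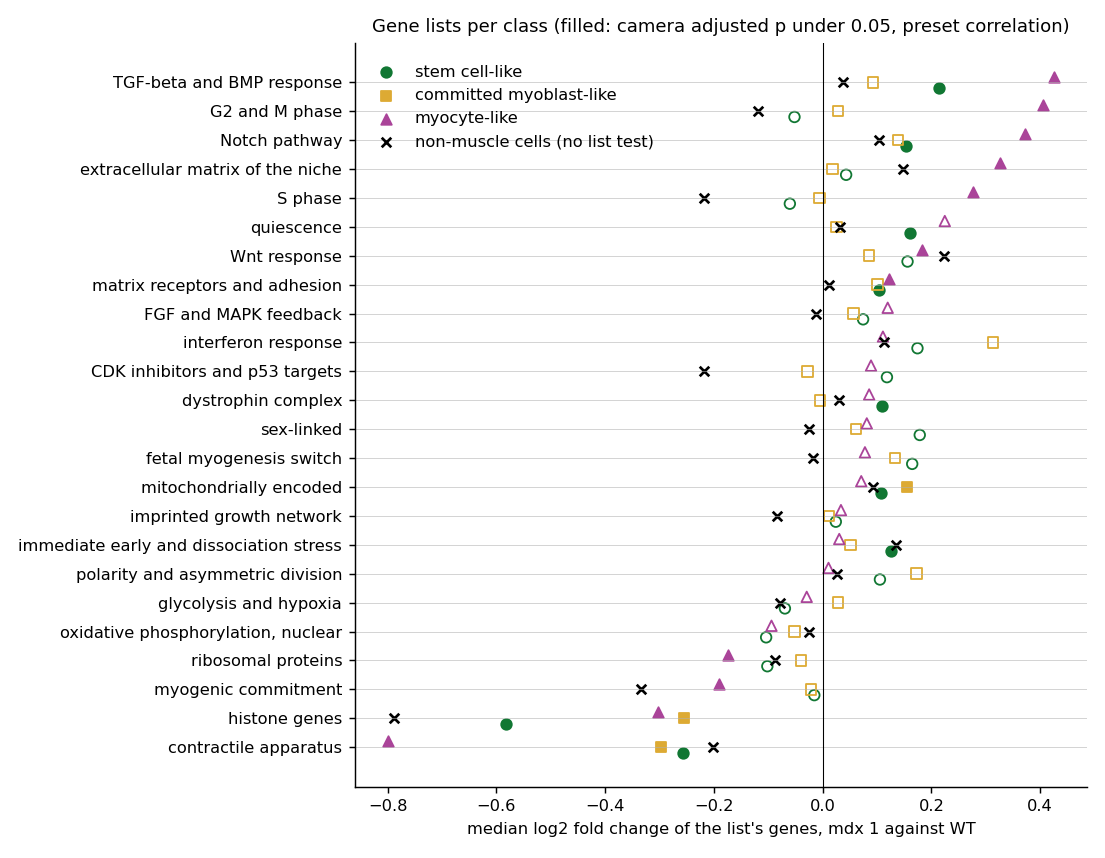
Points give the median log2 fold change (mdx 1 against WT) of each gene list in the 3 myogenic classes, filled where the camera adjusted p with the preset correlation was under 0.05, and crosses give the medians in non-muscle cells, where lists were not tested. The contractile apparatus stands at -0.80 in the myocyte-like class, and the histone genes at -0.58 in the stem cell-like class and -0.79 in non-muscle cells.

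Many of the changes of the stem cell-like class were also present in the few non-muscle cells of the same libraries, which are fibroblast-like, chondrocyte-like and immune-like. Of 291 changed genes with a value in both, 80.8% (75.7 to 85.1) had the same sign in non-muscle cells, against 61.6% of 10228 genes that did not pass, and the slope of the non-muscle on the stem cell-like log2 fold change was 0.69 (0.57 to 0.83). Both intervals treat genes as independent, which genes of the same libraries are not. The 61.6% is not matched on the size of the fold change. The respiratory subunit gene mt-Nd3, the heat shock genes Hspa1a and Hspa1b and the short ribosomal gene Rps29 rose in both. Fosb and the histone genes Hist1h1b and Hist1h1e fell in both. Hes1, with 0.33 in non-muscle cells, did not pass there, and whether the classes differ in it was not tested. In non-muscle cells 106 of 10851 genes passed by edgeR (66 higher, 40 lower).

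**Figure D4:**
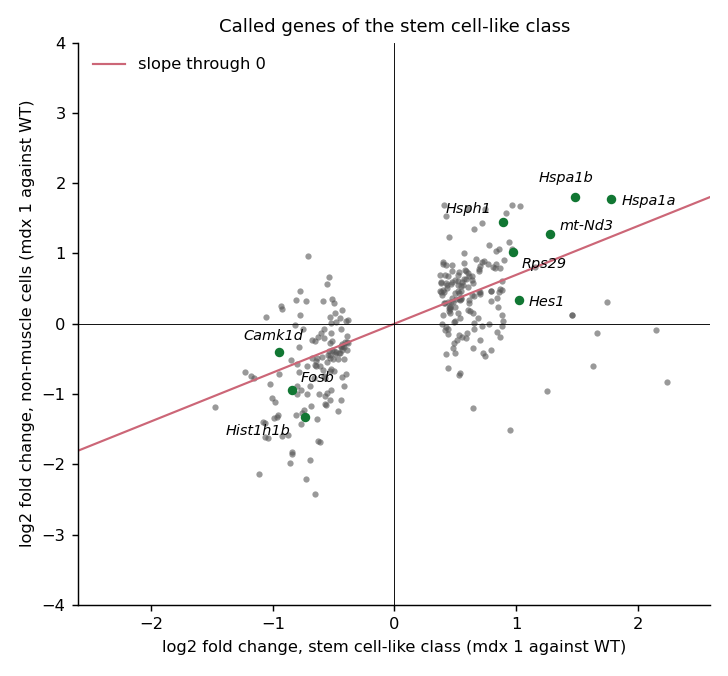
Each point is 1 of 291 genes past the edgeR threshold in the stem cell-like class, with its log2 fold change (mdx 1 against WT) there on the x axis and in non-muscle cells on the y axis. The line through 0 has a slope of 0.69, and 80.8% of the genes have the same sign in both.

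In the committed myoblast-like class of mdx 1, Hes1, Hspa1a, mt-Nd3, Fosb and Camk1d changed the same way as in the stem cell-like class. Hes1 rose from 29.8 and 21.8 to 48.7 CPM (log2 fold change 0.92), Hspa1a by 1.53 and mt-Nd3 by 1.26. Ctnna2, a catenin gene, and Kcnq5, a potassium channel gene, rose by 0.95 and 0.90. Fosb fell from 56.4 and 56.2 to 24.8 CPM (-1.18), its partner gene Fos fell by 0.66 and Camk1d, a calcium-dependent kinase gene, fell by 0.90. Myog and Myod1 had log2 fold changes of 0.11 and 0.13 and did not pass. By edgeR 74 of 12144 genes passed (50 higher, 24 lower), and DESeq2 called 6, among them Camk1d and mt-Nd3. The count was 21 with thinned cells, 221 at resolution 2, 326 with components centred per library and 335 with classes from marker scores. With WT 1 or WT 2 set apart in place of mdx 1, the common biological coefficient of variation was again higher (9.16% and 9.77% against 7.68%). Of 19 contractile apparatus genes 0 passed (0 adjusted over the list alone), yet the list moved down (median -0.30; camera adjusted p = 0.00145, and adjusted p = 0.895 with an estimated correlation). Of 15 histone genes, 3 fell and 12 did not pass (0 and 4 adjusted over the list alone, median -0.25; camera adjusted p = 0.00145, or 0.0856 with thinned cells, and adjusted p = 0.895 with an estimated correlation). Of 13 mitochondrially encoded genes, 1 rose and 12 did not pass (2 and 0 adjusted over the list alone, median 0.16; camera adjusted p = 0.00169, and adjusted p = 0.895 with an estimated correlation), a call lost with the stricter filter or classes from scores. The other 21 lists did not pass, and the signs of median and camera differed for CDK inhibitors, the dystrophin complex, oxidative phosphorylation, ribosomal proteins, myogenic commitment and the imprinted network.

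In the myocyte-like class of mdx 1, most contractile apparatus genes (19 of 24) and the fusion genes Mymk and Mymx fell, while 28 of 52 G2 and M phase, 7 of 24 extracellular matrix and 3 of 17 Notch pathway genes rose. Myh3, the embryonic myosin heavy chain, fell from 75.1 and 97.1 to 35.6 CPM (log2 fold change -1.28, SE 0.14, edgeR adjusted p = 1.84e-16), and Mymk, the membrane activator of myoblast fusion, from 197 and 232 to 124 CPM. Cdkn1a, which enforces cell cycle exit, fell from 317 and 329 to 217 CPM, and Hmgb2, a chromatin protein gene of dividing cells, rose from 848 and 837 to 1312 CPM. Tnc and Col3a1, which encode matrix proteins, rose by 0.98 and 0.95, and Hes1 rose from 8.65 and 6.81 to 19.4 CPM. Pax7 rose from 63.6 and 47.9 to 82.1 CPM, while Myog had 1863, 1816 and 1611 CPM and Myod1 a log2 fold change of 0.12, and neither passed. Hes1, Pax7, Hey1, Heyl and Egfr had far higher levels in the stem cell-like class. Free RNA of stem cell-like cells is therefore not excluded for their rises in this class.

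By edgeR 812 of 13796 genes passed, 483 higher and 329 lower. DESeq2 called 60 genes, all among the 812, and kept Myh3, Myl1, Mymk, Mymx, Cdkn1a, Hmgb2, Col15a1, Tnc, Nrg1, Fosb, Klf2 and Hes1. The count was 217 with thinned cells, 263 and 370 at resolutions 0.5 and 2, 440 with the stricter filter and 43 with classes from marker scores, where 799 of 809 genes kept their sign. With WT 1 or WT 2 set apart in place of mdx 1, the common biological coefficient of variation was again higher (15.2% and 12.4% against 7.95%). Different clusters filled the class, since clusters 5 and 8 held most of it in WT 2 and clusters 5 and 6 in WT 1 and mdx 1, and contractile, fusion and cell cycle genes define these clusters.

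Of 24 contractile apparatus genes, 0 rose, 19 fell and 5 did not pass (0 and 22 adjusted over the list alone, median -0.80; camera adjusted p = 1.89e-42, and adjusted p = 0.649 with an estimated correlation). Tnnt3 fell by 1.30, Myl1 by 1.15 and Mylpf by 1.11, from 38.3, 278 and 411 CPM in WT 1. Taken alone, clusters 5, 8 and 6 had medians of -0.42, -0.40 and -0.20 for the contractile apparatus list. In cluster 15, with 54 cells in mdx 1, Tnnt3, Myl1, Mylpf and Ckm, the muscle creatine kinase gene, were above 0 (0.08, 0.18, 0.21 and 0.02). With clusters 5, 6, 8 and 15 weighted equally, the contractile median was 0.05, with 11 genes lower and 13 higher. CPM values were averaged over the clusters before logs, so cluster 15, with the highest myocyte score (4.12), weighs most in it. The 0.05 therefore does not show that the fall ends with an equal makeup. Of 19 myogenic commitment genes, 5 fell and 14 did not pass (1 and 5 adjusted over the list alone, median -0.19; camera adjusted p = 0.00381, and adjusted p = 0.649 with an estimated correlation), among them Mymk (-0.79), Mymx (-0.66) and Tspan33 (-0.60). Of 52 G2 and M phase genes, 28 rose and 24 did not pass (40 and 0 adjusted over the list alone, median 0.40; camera adjusted p = 4.54e-22, and adjusted p = 0.649 with an estimated correlation), and of 42 S phase genes 9 rose and 33 did not pass (19 and 0 adjusted over the list alone, median 0.28; 2.25e-09, and adjusted p = 0.649 with an estimated correlation). Gtse1 and Aurka rose by 1.44 and 0.59 and the replication genes Hells and Pcna by 0.49 and 0.48. The G2 and M phase call ended with the stricter filter (adjusted p = 0.272), and in cluster 5 alone the list moved down (median -0.18). The S phase call ended at resolution 2 (adjusted p = 0.0607). With mdx 1 given the WT weights of clusters made without contractile and myocyte marker genes, the medians were 0.04 for the G2 and M phase, 0.01 for the S phase and 0.16 for the extracellular matrix list. With these weights the log2 fold changes were -0.46 for Myh3, -0.29 for Myl1, -0.16 for Mylpf, -0.33 for Tnnt3, -0.47 for Mymk, -0.33 for Cdkn1a and 0.21 for Aurka, against 1.18 for Hes1, 0.71 for Tnc and 0.72 for Col3a1. Histone genes went the other way: of 15, 1 rose, 6 fell and 8 did not pass (1 and 8 adjusted over the list alone, median -0.30; camera adjusted p = 0.0171, and adjusted p = 0.649 with an estimated correlation).

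Of 24 extracellular matrix genes, 7 rose and 17 did not pass (13 and 1 adjusted over the list alone, median 0.33; camera adjusted p = 3.47e-08, and adjusted p = 0.649 with an estimated correlation), with Col15a1 from 33.1 and 33.2 to 58.6 CPM and Postn up by 1.13, a gene at -0.14 with thinned cells. Fibroblast-like cells were also a larger share of mdx 1. Of 17 Notch pathway genes, 3 rose (Hes1 1.34, Hey1 1.23 and Heyl 0.69) and 14 did not pass (3 and 0 adjusted over the list alone, median 0.37; camera adjusted p = 0.00167, or 0.117 with thinned cells, and adjusted p = 0.649 with an estimated correlation). Of 21 TGF-beta and BMP response genes, 4 rose and 17 did not pass (8 and 0 adjusted over the list alone, median 0.43; camera adjusted p = 3.93e-05, and adjusted p = 0.649 with an estimated correlation), among them the BMP-induced inhibitors of differentiation Id2 (0.66) and Id3 (0.60). Of 23 matrix receptors 2 rose (3 and 0 adjusted over the list alone, median 0.12; 0.0134), of 15 Wnt response genes 1 rose, the receptor gene Lgr5 (4 and 0 adjusted over the list alone, median 0.18; 0.0274), and of 49 ribosomal protein genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, median -0.17; 0.0171). For these 3 lists camera's adjusted p was 0.649 with an estimated correlation, and each call was also lost in other settings. Of 25 polarity genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.01; camera adjusted p = 0.144): Egfr rose from 2.34 and 2.95 to 5.71 CPM and Vangl2, a planar polarity gene, by 0.72, while Scrib, a basal polarity gene, fell from 79.8 and 80.6 to 54.0 CPM. In the dystrophin complex (20), Sgcd, a sarcoglycan gene, rose by 0.64 and Cav3, a muscle caveolin gene, fell by 0.69, and 18 did not pass (1 and 1 adjusted over the list alone, median 0.09; camera adjusted p = 0.542). Quiescence genes (16) had 5 that rose, among them Cd34 (1.28), and 1 that fell (7 and 1 adjusted over the list alone, median 0.22; camera adjusted p = 0.0508). Immediate early genes (30) had 8 that rose and 5 that fell (9 and 7 adjusted over the list alone, median 0.03; camera adjusted p = 0.126): Hspa1a rose by 1.82, and Fosb and Klf2, early response transcription factors, fell by 1.64 and 1.49. Utrn (0.33), Notch3 (0.47), Myf5 (0.64), Mki67 (0.27), Pard3 and Mark2 did not pass. Median and camera differed in sign for the CDK inhibitor, fetal switch, glycolysis and imprinted lists, which did not pass.

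Over all myogenic cells, which also carry the different shares of the classes, Myog and 21 of 26 contractile apparatus genes fell, and Hes1 and Calcr rose. Myog fell from 479 and 545 to 310 CPM (log2 fold change -0.72, SE 0.15, edgeR adjusted p = 5.44e-05), Mymk from 48.2 and 66.3 to 22.5 CPM and Cdkn1a from 98.9 and 116 to 65.4 CPM. Hes1 rose by 1.17, Calcr by 0.90 and Socs2, a feedback inhibitor of cytokine signals, by 0.90. Egfr rose from 43.7 and 45.3 to 60.4 CPM, and Pax7 and Myf5, with log2 fold changes of 0.19 and 0.13, did not pass (adjusted p = 0.532 and 0.637). By edgeR 959 of 17739 genes passed (420 higher, 539 lower), DESeq2 called 175, 173 of them among the 959, and with thinned cells 381 passed. With WT 1 or WT 2 set apart in place of mdx 1, the common biological coefficient of variation was again higher (14.1% and 11.9% against 8.10%).

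Of 26 contractile apparatus genes 21 fell and 5 did not pass (1 and 22 adjusted over the list alone, median -0.999; camera adjusted p = 6.02e-69, and adjusted p = 0.568 with an estimated correlation), led by Myh3 (-1.91), Myl1 (-1.66) and Klhl41 (-1.61), and of 20 myogenic commitment genes 1 rose and 7 fell (1 and 9 adjusted over the list alone, median -0.23; 4.38e-10, and adjusted p = 0.568 with an estimated correlation). Of 27 polarity genes, Egfr (0.44), Vangl2 (0.43) and Gpsm2 (0.38), which orients the mitotic spindle, rose, Scrib (-0.54) fell and 23 did not pass (4 and 1 adjusted over the list alone, median 0.05; camera adjusted p = 0.143). In the dystrophin complex (20), 2 rose, among them Dtna (0.41), 2 fell, among them Cav3 (-0.77), and 16 did not pass (2 and 2 adjusted over the list alone, median 0.12; adjusted p = 0.245). Of 19 Notch pathway genes 4 rose, Hes1, Hey1, Hey2 and Nrarp, and 15 did not pass (4 and 1 adjusted over the list alone, median 0.19; camera adjusted p = 0.000219). Histone genes (9 of 15 fell), immediate early genes (10 of 33 rose, 4 fell), extracellular matrix (1 of 26 rose), matrix receptors (3 of 23 rose), quiescence (3 of 18 rose, 1 fell) and TGF-beta genes (5 of 23 rose) also passed camera (adjusted p = 1.04e-08, 7.39e-10, 0.00357, 0.00783, 0.00519 and 2.64e-06). For these 7 lists the adjusted p was 0.568 with an estimated correlation. The signs of median and camera differed for the fetal switch, glycolysis and imprinted lists, which did not pass.

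Between the stem cell-like and the myocyte-like class, in classes clustered without these lists, 18 of 20 dystrophin complex, 17 of 25 polarity and 15 of 19 Notch genes passed, against 10393 of 14677 over all genes. Dmd itself fell from 270 ± 43.2 to 120 ± 19.2 CPM (SD, n = 3 libraries; log2 fold change -1.17, SE 0.05, edgeR adjusted p = 9.44e-12), while Cav3 rose from 7.06 ± 0.687 to 37.8 ± 10.2 CPM. Egfr fell from 65.3 ± 8.97 to 3.94 ± 1.93 CPM, and the Notch targets Hes1 and Hey1 and the receptor gene Notch3 fell by 2.89, 3.24 and 3.63. Scrib rose from 17.1 ± 0.421 to 76.8 ± 16.3 CPM, Pard3 from 231 ± 16.6 to 411 ± 17.8 CPM, and Dll1, a Notch ligand gene, by 2.42. Of 20 dystrophin complex genes 7 were higher and 11 lower in the myocyte-like class and 2 did not pass. Of 25 polarity genes 8 were higher, 9 lower and 8 not past the threshold, among them Aurka (0.21, adjusted p = 0.0635), and of 19 Notch genes 5 were higher, 10 lower and 4 not past. Adjusted over the list alone the counts were 7 and 11, 8 and 9, and 5 and 10. Higher were also Sgcb (1.01), Numbl (0.99), the Notch effector gene Rbpj (1.02) and Megf10 (2.04), a regulator of satellite cell proliferation. Lower were also Lama2 (-1.05), the laminin chain of the muscle basement membrane, Utrn (-0.40), Dtx4 (-3.62), Jag1 (-1.77) and Heyl (-2.31). Dll1 was among the naming markers. Over all genes 10393 of 14677 passed (5143 higher, 5250 lower), as befits classes made from the same counts, and with the WT libraries alone 19, 18 and 15 members of the 3 lists passed.

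**Figure D5:**
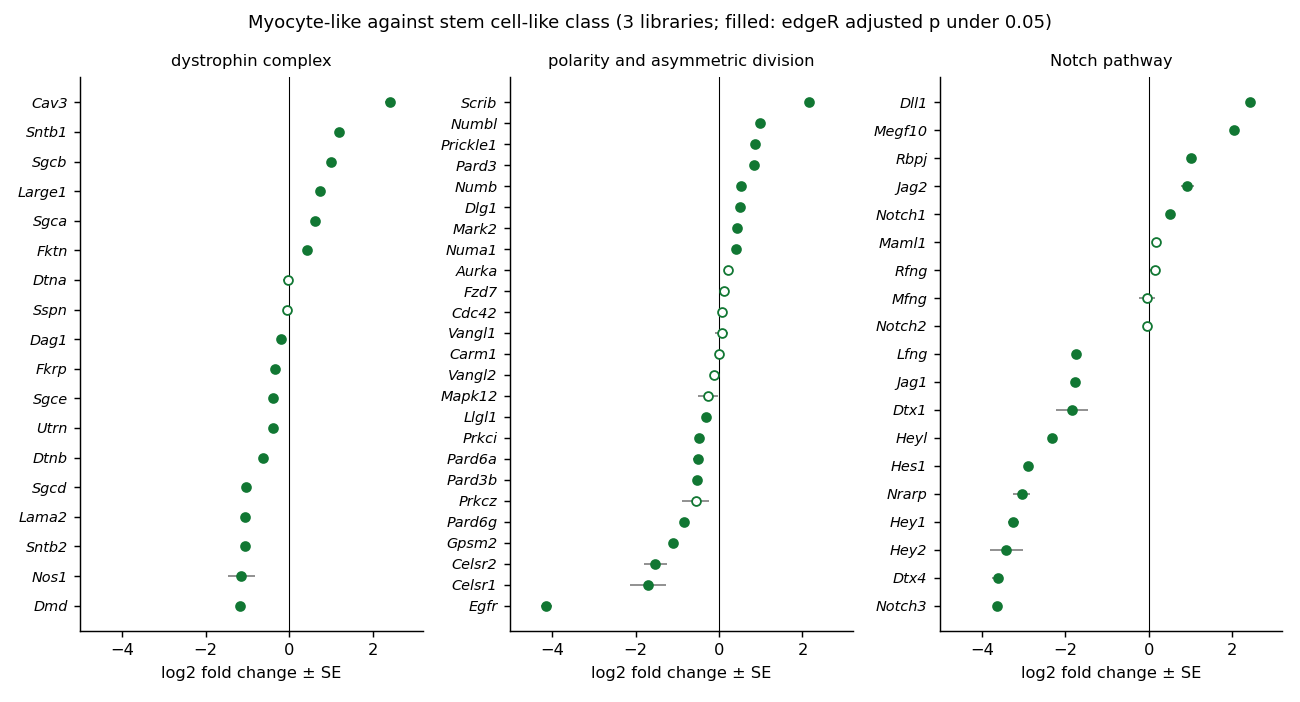
Points give the log2 fold change with its SE of genes of the 3 lists from the stem cell-like to the myocyte-like class over 3 libraries, filled where edgeR's adjusted p was under 0.05. Dmd stands at -1.17, Cav3 at 2.41, Egfr at -4.13, Scrib at 2.16 and Notch3 at -3.63.

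The step from the stem cell-like to the myocyte-like class differed in mdx 1 for single genes of several kinds, and no gene list was tested on this difference. The interaction was -1.36 for Ckm, -1.01 for Acta1, -0.92 for Tnnt3 and for Myom1, a sarcomere M-band gene, -1.64 for Filip1 and -1.27 for Klf2. It was 1.35 for S1pr3, a sphingosine phosphate receptor gene, 1.07 for Cav1, 1.06 for Cd34 and 0.98 for Prkcq, a protein kinase C gene. Cdkn1a, Scrib and Dtna had interactions of -0.72, -0.55 and -0.75, and Pax7, Mki67, Aurka and Tnc of 0.49, 0.42, 0.55 and 0.75, all past the threshold, while Dmd had -0.03 (adjusted p = 0.930). By edgeR 475 of 15302 genes passed, 272 with a positive and 203 with a negative interaction. With RLE size factors 484 passed (326 and 158), with DESeq2 56, at resolution 2 159, with centred components 273, with the stricter filter 92 and with the Tagln clusters joined 303.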

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

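The comparison of the step between classes was planned, and the tests of explanations in this part, with the weighting of clusters, were chosen after the results were seen.

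The step from the stem cell-like to the myocyte-like class differed in mdx 1 for 475 genes by the interaction term, a difference between the groups under the same contrast, and no gene list was tested on it. The contractile apparatus genes, which encode the motor and scaffold of the sarcomere, had a median log2 fold change of -0.72 (cells resampled, -0.88 to -0.58) over the myocyte-like class when 14 clusters were made without them and without the myocyte markers. With mdx 1 given the mean WT weights of these clusters the median was -0.22 (-0.34 to -0.06), with 16 of 24 genes lower and 5 higher, so part of the difference may lie in which cells fill the class. The G2 and M phase median went from 0.48 to 0.04 and the S phase median from 0.34 to 0.01, and the extracellular matrix median from 0.38 to 0.16, while the Notch pathway (0.35 to 0.28) and the TGF-beta and BMP response (0.41 to 0.32) moved less. With equal weights of clusters 5, 6, 8 and 15 the contractile median was 0.05, with 11 genes lower and 13 higher. The other medians were then 0.04 for G2 and M phase, 0.06 for S phase, 0.30 for extracellular matrix, 0.32 for Notch and 0.32 for TGF-beta. Those clusters were made with the contractile genes, and cluster 15 held 54 cells of mdx 1. Their CPM values were averaged before logs, so cluster 15 weighs most in the contractile median. A change within cells and a different makeup cannot be told apart for the contractile genes, because cells that have gone less far differ in both and the smallest mdx 1 cluster held 12 cells.

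Outside the kept cells, 24.4% of the barcodes of mdx 1 failed the cell filters, against 16.6% and 10.8% in WT 1 and WT 2. The lower share of differentiating cells in mdx 1 could come from such a loss, and the tests argue against this as its source: over all barcodes, thinned to 500 UMIs, Myog, the factor of terminal differentiation, was detected in 9.38% (8.89 to 9.89) in mdx 1 against 13.5% and 15.02%, and in the barcodes that failed it was detected in 9.35% against 12.8% and 13.1%. Without doublet removal the myocyte-like share was 12.8% in mdx 1 against 19.2% and 23.8%, which argues against doublet removal. An earlier stage of the mdx 1 fetuses stays open, since the fetal myogenesis switch list had a median of 0.16 and a camera adjusted p of 0.363 in the stem cell-like class with 9 of 11 genes higher and 2 lower, a lean away from the fall that an earlier stage predicts, although the list did not pass. The GFP gate, a loss of fused or fragile cells before capture and an effect of the genotype on differentiation stay open too, as untested, with 1 mdx library.

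Unnamed clusters of low UMI counts, outside the classes compared, held 6.03% of the kept cells of mdx 1 against 3.74% and 4.15% in WT 1 and WT 2.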

How the results depend on the processing

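The alternatives with the Tagln clusters joined, single clusters, classes from marker scores for gene counts, haemoglobin droplets removed and WT libraries alone were chosen after the data were seen, and the others were planned. No paired analysis was possible because the labels pair no WT library with an mdx one. Without droplets of haemoglobin UMIs all 454 named gene values, and with RLE size factors 452 of 454 (2 lost their call), kept direction and side of the threshold, against 298 with DESeq2 (156 lost their call, none changed sign), 418 without doublet removal, 391 with the stricter filter, 388 without a filter on low counts, 345 with components centred per library and 337 with thinned cells. The number of genes changed in the stem cell-like class (426) was 133 with thinned cells, 12 with centred components, 38 with DESeq2, 4 without a filter on low counts and 258 in cluster 0 alone. In the committed myoblast-like class (74) it was 21 with thinned cells, 221 at resolution 2, 326 with centred components, 335 with classes from marker scores and 6 with DESeq2. In the myocyte-like class (812) it was 217 with thinned cells, 263 and 370 at resolutions 0.5 and 2, 440 with the stricter filter, 43 with classes from marker scores, 60 with DESeq2, and 158, 104, 125 and 86 in clusters 5, 6, 8 and 15 alone. In all myogenic cells (959) it was 381 with thinned cells and 175 with DESeq2. The interaction (475) gave 159 at resolution 2, 273 with centred components, 92 with the stricter filter, 303 with the Tagln clusters joined and 56 with DESeq2. Single clusters and thinned cells have fewer counts. For the other settings the cause was not tested. With an estimated correlation 0 of the 9 moved lists passed in the stem cell-like class and 0 of the 9 in all myogenic cells. That setting rests on the residual degree of freedom of the WT pair, so few lists could pass it. The mdx 1 excess in the stem cell-like share (8.20 points) was 3.07 with centred components, 9.81 at resolution 0.5 and 11.1 with classes from marker scores. The committed myoblast-like difference (-0.017 points) was 1.02 with centred components, -0.445 without doublet removal, -0.356 at resolution 2, -2.90 with classes from marker scores and -1.62 with the stricter filter, and the difference in the share of stem cell-like cells in S, G2 or M phase was -1.21 with classes from marker scores. The cause was not tested. Leaving out a WT library gave 7.47 to 8.94 points for the stem cell-like share, -0.125 to 0.0907 for the committed myoblast-like, -10.6 to -6.11 for the myocyte-like, and 0.935 to 1.16 for the non-muscle. It gave -9.22 to -5.46 points for the share of myogenic cells with a UMI of Myog, 4.14 to 6.45 for the share of myogenic cells with a UMI of Pax7, 0.904 to 2.06 for the share of myogenic cells with a UMI of Myf5, -0.189 to 0.873 for the share of myogenic cells with a UMI of Myod1, -2.04 to -1.44 for the phase share and 49 to 50 changed list genes across classes. Of the called genes of the myocyte-like class, 121 of 681 tested in cluster 15 alone had the other sign. In clusters 5, 6 and 8 alone the values were 73 of 760, 44 of 779 and 42 of 716. Among named genes called in the main or the alternative fit, values on the other side of 0 in this class were, in cluster 15 alone, Tnnt3 0.078, Myl1 0.18, Mylpf 0.21, Ckm 0.022, Eno3 0.40, Ccng1 0.24, Cdkn2d -0.17, Hells -1.09, Tgfb2 -0.11, Id3 -0.24, Hmgb2 -0.021, Id2 -1.69, Col18a1 -0.11 and Nrg1 -0.83. In cluster 6 they were Myh3 0.39, Cav3 0.27 and Ccng1 0.085. In cluster 5 they were Fbxl22 0.35, H1fx -0.30, Aurka -0.26 and Kif23 -0.19, and in cluster 8 H1fx -0.11 and Kif23 -0.30. At resolution 2 Rad51ap1 was -0.040, with the stricter filter Kif23 -0.10, with classes from marker scores Lgr5 -0.0068 and with thinned cells Postn -0.14. Without WT 2 and without WT 1, Hist1h2ap was -1.39 and 0.51 in the stem cell-like class and -1.28 and 0.60 in all myogenic cells. Without WT 1, Rpl9 was 0.11 in all myogenic cells. Hist1h2ap turned because WT 1 held the high value of Hist1h2ap. Resolution 0.5 has no committed class, and the interaction without a WT library and gene counts with 1 library on each side have no residual degrees of freedom, so no test was possible. Among the simulated myogenic classes, depth limits calls of 1.5-fold changes most in the committed myoblast-like class, which had 6034781, 6345117 and 5385715 UMIs. The non-muscle sums were smaller, at 1033075, 1156751 and 1590574 UMIs, and were not simulated.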

Other observations

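All tests of explanations in this part, and the choice of the 3 genes singled out first, were made after the results were seen.

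A few genes were close to present or absent by library. Rftn1, which encodes a lipid raft protein (chromosome 17, 49992257 to 50190674), had 0, 0 and 48 UMIs in the stem cell-like class of WT 1, WT 2 and mdx 1, at least 30.5-fold higher in mdx 1 with a floor of 3 counts over the WT group, and 1, 4 and 67 UMIs in all myogenic cells. Slc15a2, a peptide transporter gene (chromosome 16, 36750177 to 36784962), had 3, 4 and 116 UMIs in the stem cell-like class and 4, 4 and 183 in all myogenic cells. Iqcm, which encodes a calmodulin-binding motif protein (chromosome 8, 75448694 to 75984503), went the other way with 68, 76 and 5 UMIs, and 114, 114 and 8 in all myogenic cells. None of the 3 lies on the X chromosome, where Dmd lies. Whether they reflect strain differences between the WT and mdx lines was not tested and cannot be read from the counts.

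The immune-like and connective tissue cells differed as well, as a mix of types. S100a8 and S100a9, which encode the calprotectin of neutrophils, rose by 2.82 and 2.23, with S100a8 at 106, 0.875 and 367 CPM, and the chemokine genes Ccl3 and Ccl4 rose by 2.38 and 2.46. Mrc1 and Lyve1, receptors of resident macrophages, fell by 2.43 and 1.91, and the cartilage genes Chad, Matn4 and Ucma fell by 1.85, 1.80 and 1.52. These sums hold 143, 176 and 236 cells, so a shift in the mix of types changes them, and S100a8 differed widely between the WT libraries. Myog fell by 1.36 in the same cells, which should lack it.

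The stress, histone and short-transcript changes of the stem cell-like class may belong to the mdx 1 library as a whole, in handling or preparation. Of 291 changed genes, 80.8% (75.7 to 85.1) went the same way in non-muscle cells with a slope of 0.69, against 61.6% of the genes that did not pass. Such a shift was proposed from this same observation, so the values leave it open and are no independent support for it. The intervals in this paragraph treat genes as independent, which genes of the same libraries are not. Free RNA of muscle cells in non-muscle droplets is argued against as the whole carrier: in the 173 genes with a WT level in non-muscle cells at least that of the stem cell-like class the slope was 0.54 (0.39 to 0.71). Muscle RNA was in these droplets, with Myog at 78.2, 47.2 and 24.2 CPM against 479, 545 and 310 CPM in all myogenic cells, a background too low to carry that slope in genes of like level, and a smaller contribution stays open. Transcript length is argued against as the whole cause, since taking off the median of the length bin lowered the median absolute log2 fold change by 1.71% (0.667 to 0.656 in 388 genes). Over 13022 genes, length correlated with the log2 fold change of mdx 1 (Spearman's rho 0.17) and with that of WT 2 against WT 1 (0.24). A smaller part of length stays open. A systemic effect of the genotype on all limb cells stays open, as untested, and 1 mdx library cannot separate it from the library.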
